A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

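Total RNA of log-phase asynchronous *S. pombe* cells was sequenced on an Illumina HiSeq instrument, per the labels' protocols, in 2 WT and 2 set2d libraries. Per the submitters' processing notes, STAR 2.5.4b and featureCounts 1.5.0-p1 were used with the genome build ASM294v2. The normalization method, the annotation, the strand setting and the treatment of reads that overlap several genes are not given in the sources used here. The deposited table gives 1 log2 value for each of 6986 genes in each of the 4 libraries. From the values, the authors' log2 scale is that of normalized counts floored at 10: the lowest value in every column is the log2 of 10. At the floor were 392 and 402 genes in WT replicates 1 and 2 and 367 and 363 in set2d replicates 1 and 2, and 317 genes were there in all 4. A fold change against a group at the floor is a lower bound, and changes of genes just above it are understated.

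The depth was sought in the low values. In set2d replicate 1, all of the 684 genes between 10 and 400 (100%) fell on whole multiples of 1.06 normalized counts within a tolerance of 0.012, where chance gives 2.26%. In that library the floor is then 9.42 counts and a level of 50 is 47.1 counts, with a counting error of 14.6%. This covers counting error only. In the other 3 libraries no single step held across levels. In set2d replicate 2 a step of 0.547 held for 100% of genes at levels of 10 to 100 but for 9.26% at 200 to 400. For the WT libraries genes were ordered by the geometric mean of their value and that in set2d replicate 1. In WT replicate 1 the step was 1.38 at low means and 1.10 at means of 91.7 to 117. In WT replicate 2 it was 0.645 at low means and 0.67 at means of 50.1 to 94.7. Whole counts were therefore not recovered across genes there and their depth is unknown. A scaling by the authors that depends on level, with set2d replicate 1 as the reference, would give such steps. It can move changes of genes at one level relative to another.

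Reads of overlapping genes appear to have been counted for both. The gene adh1 had 855184 normalized counts in WT replicate 1, and SPCC13B11.02c on the opposite strand had 855154. Changes of a gene and its antisense partner can therefore not be told apart. Locus tags were matched to the ASM294v3 annotation, 6838 of 6986, and 148 were left unmatched, 2 of them because the tag has been reassigned. Because that assembly differs from the authors' build, it was used for names, gene neighbours, gene lengths and distance classes from chromosome ends, and no coordinates are given. Near-identical copies, 131 genes, were found with BLAST 2.17.0 at 95% identity over at least 50% of the length.

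The design had assumed log2 of the value plus 1. Since the table was already on a log2 scale, limma 3.58.1 (R 4.3.3) was run on the deposited log2 values, with a mean-variance trend, on genes above the floor in at least 2 libraries. This kept 6633 genes and left out 353. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 2 residual and 6.16 prior degrees of freedom. Means ± SD are of normalized counts, and log2 changes are differences of mean log2 values, set2d minus WT. The procedure was tested on simulated data for the 6633 genes, with 200 changed among those with a mean level above 50. It recovered 6.4% of genes changed by 0.5 on the log2 scale, 49.6% by 1, 79.2% by 2 and 98.0% by 4, and 3.01% of its calls were false. Recovery at lower levels was not covered, nor a number of changed genes as large as the 951 called in the data. Simulated errors were independent between genes and libraries. Deviations shared between genes or libraries were not covered, so the share of false calls in the real data may differ.

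Before the data were examined, 26 gene lists, the tests of position and feature class, the processing alternatives and the rule for named genes were fixed. The rule takes set2, then the 12 largest increases and 12 largest decreases by log2 change among genes that passed, whose libraries separate by group and whose mean in the higher group is at least 50, then up to 4 members of each list with the largest absolute change. If fewer than 5 pass in a direction, the 5 with the smallest unadjusted p are taken. Lists were tested with limma's camera with a preset correlation of 0.01 and with an estimated one, adjusted over the lists. With the preset correlation 7 lists passed, and with the estimated one 0 did. The test with an estimated correlation rests on the 2 residual degrees of freedom and has little power. By it the subtelomeric list, with 77 of 100 members higher, had a camera p of 0.0236, or 0.371 adjusted. Not passing it therefore does not show that a list was unchanged. Shares were compared with Fisher's exact test in scipy 1.17.1, with exact binomial intervals of 95%.

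The libraries of each group are numbered 1 and 2, and titles share a prefix by number whose meaning the labels do not give. Medians of the genes near the ends and of lists that passed are therefore also given within each number. Alternatives covered the pseudocount, the filter, the trend, the scaling, the window around chromosome ends, a replicate block and each library left out. A pseudocount of 1 and the removal of genes with copies, of genes at the floor in any library and of genes near the ends were added after the data were seen.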

Results

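The transcriptome of fission yeast (*Schizosaccharomyces pombe*) lacking set2 was compared with that of wild type. Set2 is the enzyme that methylates lysine 36 of histone H3 on transcribed genes. Polyadenylation status of the sequenced RNA is not given in the sources used here. There were 4 RNA-seq libraries, 2 from a wild-type strain (WT972, here WT) and 2 from a set2 deletion strain (SPKK1227, here set2d), each made from asynchronous cells in log phase at 30 °C. Values were normalized read counts per gene on a log2 scale, with every value under 10 raised to 10. The median over genes was 5175 and 5050 normalized counts in WT replicates 1 and 2, and 5347 and 5518 in set2d replicates 1 and 2. Log2 values correlated across genes at a Pearson r of 0.994 between the WT libraries, 0.989 between the set2d libraries and 0.963 to 0.969 between groups, where genes are not independent replicates. The first principal component held 78.8% of the variance and separated the groups. The second held 16.1% and separated number 1 from number 2 in both groups. Among genes between 1000 and 10000 normalized counts, the median absolute log2 difference between replicates was 0.129 in WT and 0.211 in set2d. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

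The set2 transcript itself (SPAC29B12.02c, chromosome I) fell from 9584 ± 1300 normalized counts in WT to 1852 ± 572 in set2d (SD, n = 2 in each group). This was a log2 change of -2.40 (SE 0.22, limma adjusted p = 0.00041), and both set2d libraries lay below both WT libraries. Reads were still counted for set2 in set2d. The sources used here do not say how much of the gene was removed.

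More transcripts were higher than lower in set2d. Of 6633 genes tested, 767 were higher and 184 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 288 and 64 of these changed by a log2 value of at least 1. At an unadjusted p under 0.05 the counts were 1234 higher and 638 lower. The balance and the counts depended on the fit, with 574 higher and 275 lower under quantile normalization and 499 and 103 by limma without a trend. A fit with a replicate block by number called 2227 genes, with a larger share of them lower. The labels do not show that the numbers pair the samples. Both set2d libraries lay on the same side of both WT libraries for 3830 genes, or 57.7%, where chance gives 33.3%. The number of calls depended on having all 4 libraries. Without WT replicate 1, WT replicate 2, set2d replicate 1 and set2d replicate 2, the genes higher numbered 488, 421, 324 and 354, and the genes lower 86, 68, 45 and 70. Of 39 genes named below that did not pass, the log2 change of 30 moved by over 1.5 times without at least 1 library. Their values are therefore uncertain. Of the 80 named genes that passed, the change of 2 moved by so much. A fit without 1 library has 1 library in a group and less power, so a call can be lost while the change hardly moves.

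Transcripts from most genes near the ends of chromosomes I and II rose. Of 144 tested genes within 100 kb of these ends in the ASM294v3 annotation, 113 were higher in set2d, or 78.5% (95% exact binomial interval 70.9 to 84.9). Elsewhere 645 of 6381 genes were higher, or 10.1% (9.38 to 10.9). The odds ratio was 32.4 (Fisher's exact test, two-sided, p = 1.05e-79, 2.11e-79 after adjustment over 2 tests, with genes not independent). The median log2 change near the ends was 2.25, and it was 2.27 within number 1 and 2.32 within number 2. Only 2 of the 144 were lower, against 177 elsewhere (odds ratio 0.49, Fisher's exact test, p = 0.441). These were pho84 and pho1, described with the phosphate genes, and they were singled out after their values were seen.

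The share of genes higher declined with distance from the end. On chromosomes I and II it was 80.4% of 51 genes at 0 to 50 kb, 77.4% of 93 at 50 to 100 kb, 36.7% of 109 at 100 to 150 kb and 20.8% of 120 at 150 to 200 kb. Beyond 200 kb it was 8.74% of 4957 genes. Median log2 changes in the same order were 3.20, 1.85, 0.45, 0.19 and -0.01. By end, 28 of 43 genes were higher at the left end of I, 35 of 41 at the right end of I, 28 of 32 at the left end of II and 22 of 28 at the right end of II. Chromosome III, whose ends carry the ribosomal DNA, showed a smaller share. There 10 of 39 genes within 50 kb of the assembled ends were higher, or 25.6% (13.04 to 42.13), with a median log2 change of 0.39. The share on III did not decline steadily, being 17.5% at 50 to 100 kb, 28.3% at 100 to 150 kb, 16.3% at 150 to 200 kb and 10.3% beyond. The difference between chromosomes was not tested.

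**Figure D1:**
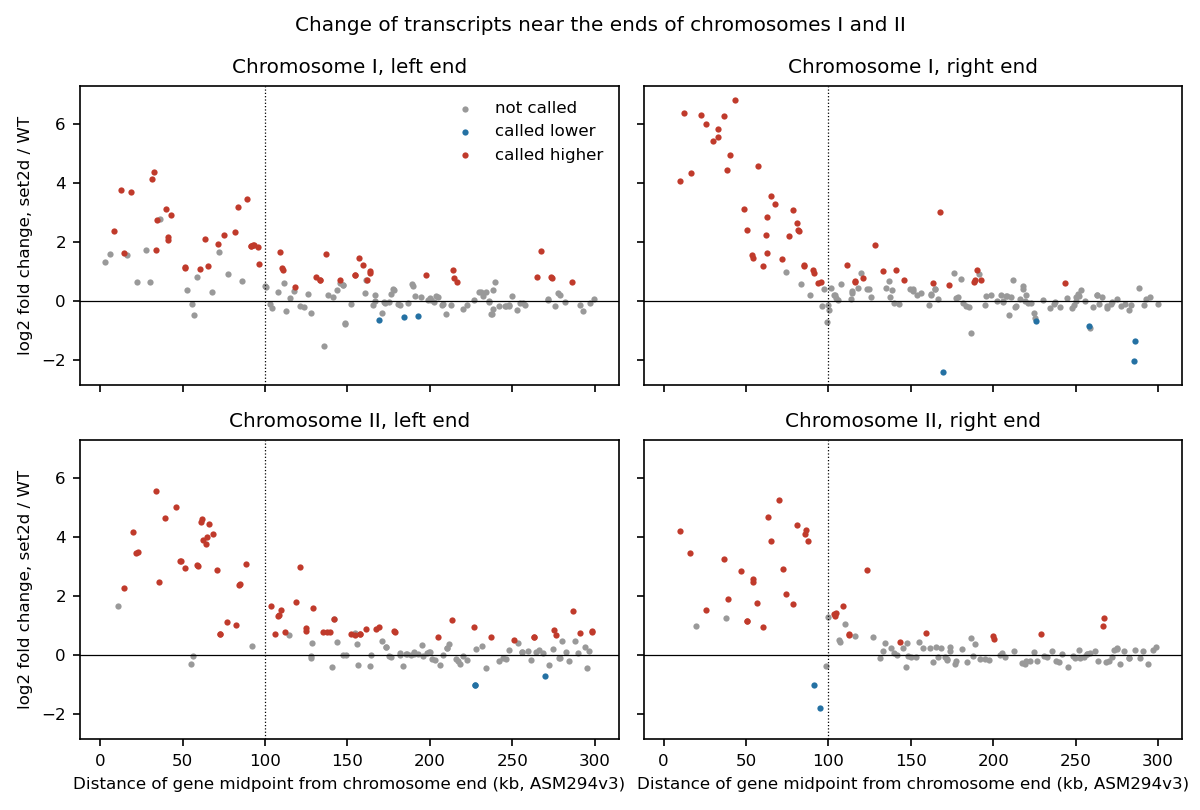
Log2 fold change (set2d over WT) of each tested gene against the distance of its midpoint from the chromosome end in kb, for the 4 ends of chromosomes I and II. Each point is 1 gene from 2 WT and 2 set2d libraries, red and blue points passed the limma test, and the dotted line marks 100 kb. Most points left of the line are red, 113 of 144 genes.

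A list of subtelomeric genes, defined before the data were examined by the prefixes of their systematic names, holds mostly the same genes, since 97 of its 100 measured members lie within 100 kb of the ends. Of the 100 members 77 were higher and 0 lower (86 and 1 at an unadjusted p under 0.05). Adjusted over the list alone, 85 were higher and 1 lower. The median log2 change was 2.71 (2.53 in number 1, 2.66 in number 2), with 17 members at the floor in both WT libraries entering at their lower bound. The list ranked above other genes by camera with a preset correlation of 0.01 (adjusted p = 1.76e-42), and had an adjusted p = 0.371 with an estimated correlation. The 3 members elsewhere had a camera adjusted p of 0.999, and none of them was higher. Of the 100, 37 have a near-identical copy, so the copy that gave the reads is uncertain.

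The 12 largest increases all came from genes within 100 kb of the ends of chromosomes I and II. At the right end of chromosome I, SPAC186.03, annotated as an L-asparaginase, went from 31.1 ± 18.2 to 3303 ± 910 normalized counts (log2 change 6.84, SE 0.43, limma adjusted p = 7.14e-05). It has a near-identical copy, SPBPB21E7.09, and is uncertain for that reason. Its neighbours rose too. The isomerase gene SPAC186.06 went from 45.9 ± 8.77 to 3560 ± 870, and pdc102 (SPAC186.09), for a pyruvate decarboxylase, from 59.1 ± 29.3 to 3557 ± 293. The hydroxyacid dehydrogenase gene SPAC186.07c went from 148 ± 44.7 to 8355 ± 611, and the lactate dehydrogenase gene SPAC186.08c from 39.1 ± 23.2 to 1534 ± 55.6. SPAC186.04c rose by 4.95 on the log2 scale. The non-coding RNA prl61 (SPNCRNA.61) rose by 5.58, but 92.1% of it overlaps SPAC186.07c on the opposite strand. SPAC750.01, an aldo/keto reductase gene, went from 256 ± 60.4 to 20250 ± 5377, a 78.8-fold increase. Closer to the same end, ftm4 (SPAC750.05c) was at or just above the floor in WT and reached 836 ± 112 in set2d, and it has near-identical copies. At the left end of chromosome II, SPBC1348.11 rose by 5.57 and the urea transporter gene SPBPB8B6.02c by 5.01 on the log2 scale. At the right end, SPBPB2B2.06c, for a phosphoprotein phosphatase, went from 460.6 ± 39.996 to 17690 ± 3034.

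**Figure D2:**
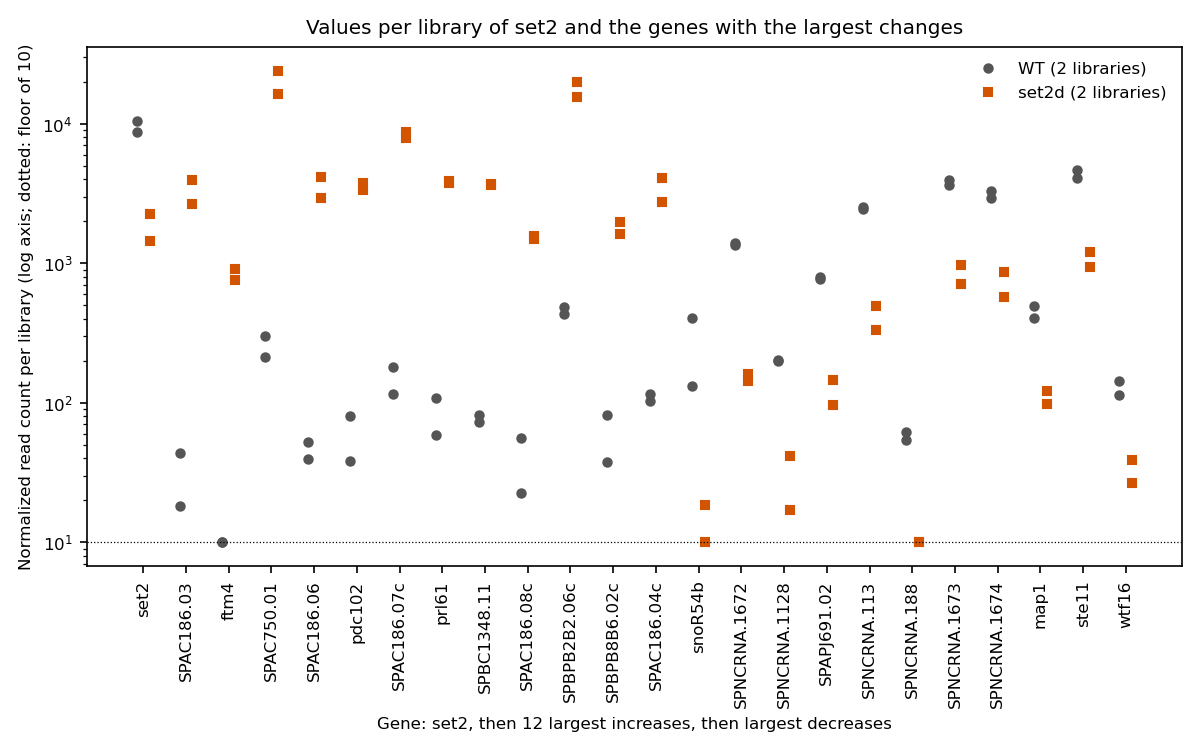
Normalized read count (log axis) of each of the 2 WT libraries (circles) and 2 set2d libraries (squares) for set2, the 12 genes with the largest increases and the remaining genes with the largest decreases. The dotted line is the floor of 10, below which no value lies. The set2 circles lie around 9584 and its squares around 1852.

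The largest decreases were smaller, and they included non-coding RNAs and regulators of mating. The small nucleolar RNA snoR54b fell from 269 ± 195 to 14.3 ± 6.08 normalized counts (log2 change -4.09, SE 0.59, limma adjusted p = 0.00312). That call was lost without set2d replicate 1 and without set2d replicate 2. SPNCRNA.1672, SPNCRNA.1673 and SPNCRNA.1674, which overlap each other on chromosome II, fell by 3.19, 2.20 and 2.14 on the log2 scale. SPNCRNA.1128 fell from 202 ± 1.94 to 29.3 ± 17.4, and SPNCRNA.113 from 2487 ± 59.3 to 415 ± 116. SPNCRNA.188 was at 57.6 ± 5.27 in WT and at the floor in both set2d libraries, at least 5.75-fold lower. Among coding genes, SPAPJ691.02, for a yippee-like protein, fell from 785 ± 13.7 to 121 ± 34.8. The MADS-box transcription factor gene map1 fell from 448 ± 62.4 to 109 ± 16.4. The transcription factor gene ste11, a central regulator of sexual differentiation, fell from 4359 ± 382 to 1072 ± 196. The meiotic drive suppressor gene wtf16 fell from 129 ± 20.6 to 32.7 ± 8.70, a call lost without set2d replicate 1.

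Several genes for heterochromatin and RNA interference factors rose. Of 15 measured, 7 were higher and 0 lower (9 and 0 at an unadjusted p under 0.05), and adjusted over the list alone 9 were higher. The chromatin remodeller gene mit1 rose from 2653 ± 143 to 7746 ± 1203 normalized counts. The histone H3 lysine 9 methyltransferase gene clr4 rose from 3996 ± 287 to 11158 ± 1118, though 54.2% of it overlaps meu6 on the opposite strand. The log2 changes of clr2 and rik1 were 0.90 and 0.87, and 91.9% of rik1 overlaps an opposite-strand gene. The call of clr2 was lost without set2d replicate 1 and without set2d replicate 2, and that of rik1 without set2d replicate 2. The list's median log2 change was 0.41, with 0.40 in number 1 and 0.42 in number 2. Its camera adjusted p was 0.00359 with the preset correlation, and the adjusted p = 0.55 with an estimated correlation.

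Some ribosome biogenesis genes also rose, and some nuclear genes for the respiratory chain and ATP synthase fell. Of 69 ribosome biogenesis genes 30 were higher and 0 lower (41 and 0 at an unadjusted p under 0.05), 37 adjusted over the list alone. Their median log2 change was 0.37, with 0.34 in number 1 and 0.45 in number 2. The gene imp4, for a protein of the U3 small nucleolar ribonucleoprotein, rose from 8189 ± 1308 to 22566 ± 69.4. The log2 changes of rrp1402, nog2 and utp18 were 1.17, 0.94 and 0.89. The call of nog2, 94.5% of which overlaps a non-coding RNA on the opposite strand, was lost without set2d replicate 1 and without set2d replicate 2. Camera gave the list an adjusted p = 6.93e-10 with the preset correlation and an adjusted p = 0.371 with an estimated correlation. Of 52 respiratory genes 9 were lower and 0 higher (20 and 0 at an unadjusted p under 0.05), and 12 were lower adjusted over the list alone. The median was -0.25, with -0.20 in number 1 and -0.38 in number 2. The ATP synthase genes atp5 and atp2 fell by 0.85 and 0.70 on the log2 scale, the latter call being lost without WT replicate 1 and without WT replicate 2. The values of atp19 and cox7 were -0.72 and -0.61 and did not pass. Camera gave an adjusted p = 4e-07 with the preset correlation and an adjusted p = 0.55 with an estimated correlation. None of the 140 cytosolic ribosomal protein genes passed the limma test in either direction (4 higher and 1 lower at an unadjusted p under 0.05, and 0 by limma without a trend), among them rpl4102 at 0.54, rpl3002 at 0.43, rpl1202 at 0.42 and rpl102 at 0.32, the last with a non-coding RNA over 75.1% of it. Their median was 0.15 in number 1 and -0.16 in number 2, 0.01 pooled, and camera gave an adjusted p = 0.613 in the downward direction. Single libraries decided this direction, down at 4.53e-13 without set2d replicate 1 and up at 6.86e-07 without set2d replicate 2.

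Several genes for the uptake of nutrients changed. Of 9 nitrogen-starvation and amino-acid uptake genes 6 were higher, also adjusted over the list alone, and the median log2 change was 0.86 (0.78 in number 1, 0.93 in number 2). The amino acid transporter gene isp5 rose from 1080 ± 103 to 2542 ± 252 normalized counts. It lies at 100 to 150 kb from the right end of I, a distance at which 36.7% of genes on I and II were higher. The log2 changes of isp4, put4 and isp7 were 1.20, 1.19 and 0.95. The calls of isp5 and isp4 were lost without either set2d replicate, and that of isp7 without set2d replicate 2. The camera adjusted p was 0.0201 with the preset correlation, and an adjusted p = 0.674 with an estimated correlation. It became 0.0592 without set2d replicate 1, 0.101 without set2d replicate 2, and 0.0651 with genes within 100 kb of the ends left out, put4 among them, 82.1% of which overlaps an opposite-strand non-coding RNA. Of 9 genes repressed by iron 4 were higher, also adjusted over the list alone, with a median of 0.70 (0.62 in number 1, 0.67 in number 2). The siderophore transporter gene str3, near the left end of I, rose from 18.4 ± 1.36 to 208 ± 76.9. The log2 changes of str1, sib1 and frp1 were 1.13, 1.06 and 0.86. The gene frp1 lies at 150 to 200 kb from the left end of II, a distance at which 20.8% of genes on I and II were higher. The call of frp1 was lost without any one of the 4 libraries and under quantile normalization, and that of str1 without set2d replicate 2. Those of str1 and sib1 were also lost by limma without a trend. The value of str1 ranged from 0.69 to 1.56 with single libraries left out. Camera gave an adjusted p = 0.0271 with the preset correlation, an adjusted p = 0.55 with an estimated correlation, and 0.0843 with genes near the ends left out.

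Transporter and adhesin genes moved in both directions. Of 14 hexose transport and glucose-repressed genes 3 were higher and 2 lower, with 4 and 3 adjusted over the list alone, and camera gave an adjusted p = 0.428. The transporter genes ght7 and ght3, both near chromosome ends, rose by 4.63 and 3.20 on the log2 scale. The transporter gene ght8 fell from 179025 ± 34628 to 76803 ± 18298, and the malic enzyme gene mae2 from 237090 ± 1527 to 105234 ± 28125. The call of ght8 was lost without set2d replicate 1. Of 3 phosphate-response genes, pho84 fell from 54638 ± 12650 to 15486 ± 662, pho1 fell from 17509 ± 3234 to 8444 ± 353 and tgp1 rose from 875 ± 158 to 1819 ± 576. All 3 passed adjusted over the list alone, the list's camera adjusted p was 0.102 (0.0468 without WT replicate 1, 0.00168 without WT replicate 2), and the calls of pho1 and tgp1 were lost without either set2d replicate, that of tgp1 also without WT replicate 2. Of 4 copper and zinc uptake genes 1 was higher, also adjusted over the list alone. This was the zinc-repressed alcohol dehydrogenase gene adh4, from 14327 ± 27.6 to 39957 ± 5559. It lies at 150 to 200 kb from the left end of I, a distance at which 20.8% of genes on I and II were higher. The values of zrt1, ctr4 and ctr5 were 1.18, 0.23 and 0.21 and did not pass, with zrt1 at 2.16, ctr4 at -0.302 and ctr5 at -0.0197 without set2d replicate 1 and zrt1 at 0.20 and ctr4 at 0.77 without set2d replicate 2. The list's camera adjusted p was 0.102, and 0.0468, 0.0126 and 0.0391 without WT replicate 1, WT replicate 2 and set2d replicate 2. Of 12 flocculation and adhesin genes 3 were higher and 1 lower, with 5 and 1 adjusted over the list alone. The gene pfl6 was at the floor in WT and at 87.2 ± 61.4 in set2d, at least 7.56-fold higher, and has a near-identical copy. The gene pfl9 rose by 2.42 and pfl7 by 1.79, and pfl3 fell by 1.40. Both pfl6 and pfl9 lie near chromosome ends. With genes there left out the list had 1 higher and 1 lower and a camera adjusted p of 0.298. The gene pfl7 lies at 100 to 150 kb from the left end of II, a distance at which 36.7% of genes on I and II were higher. The list's median was 0.45 (0.48 in number 1, 0.61 in number 2), its camera adjusted p was 0.0499 with the preset correlation and the adjusted p = 0.55 with an estimated correlation, and the call was lost under most other settings, for example at 0.0567 without set2d replicate 1 and 0.138 without set2d replicate 2.

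Genes of sexual differentiation did not move as one group. Of 8 mating induction genes 3 were lower and 1 higher, with 3 and 2 adjusted over the list alone (camera adjusted p = 0.37). Besides ste11, the meiotic regulator gene mei2 fell from 755 ± 337 to 220 ± 22.8 normalized counts and the signalling adaptor gene ste4 from 1244 ± 6.52 to 541 ± 17.5. The formin gene fus1 rose by 1.36 on the log2 scale, and 68.5% of it overlaps a non-coding RNA on the opposite strand. The calls of mei2, ste4 and fus1 were each lost without set2d replicate 1 and without set2d replicate 2, those of mei2 and ste4 also without WT replicate 1 and that of ste4 without WT replicate 2. Of 18 meiotic genes 3 were higher and 0 lower, also adjusted over the list alone (4 and 0 at an unadjusted p under 0.05, camera adjusted p = 0.388). The gene for the meiotic chromosome axis protein rec10 rose from 680 ± 22.0 to 3450 ± 620, mek1 from 287 ± 23.1 to 1171 ± 68.0 and spo5 from 392 ± 4.84 to 942 ± 66.6. The value of mei4 was 0.60 and did not pass. The call of spo5 was lost without WT replicate 2 and without either set2d replicate. Of 5 genes specific to M cells, mfm2 fell by 2.00 and mam1 rose by 0.74, the same 1 and 1 adjusted over the list alone (camera adjusted p = 0.633). The values of mfm1 at -1.37 (-2.17 without set2d replicate 1, -0.56 without set2d replicate 2) and mam2 at 0.41 did not pass. The level of mfm2 was low, 143 ± 27.2 normalized counts in WT and 36.5 ± 11.1 in set2d. That of mfm1 was nearer the floor, 52.7 ± 13.4 in WT and 23.3 ± 16.7 in set2d. The call of mfm2 was lost without set2d replicate 1, and that of mam1 without either WT replicate and without set2d replicate 2. Of 3 genes specific to P cells, map4 rose by 1.07, the only one also when adjusted over the list alone, a call lost without set2d replicate 1 (camera adjusted p = 0.156). The P-cell genes map2 and map3 were at 16559 ± 668 and 8902 ± 755 in WT and at 18641 ± 2685 and 10654 ± 978 in set2d, and did not pass, and 99.8% of map3 overlaps his6 on the opposite strand, so its level is uncertain. In both groups mfm1 and mfm2 lay far below map2. The labels give no mating type.

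Of 18 core environmental stress response genes 5 were higher and 4 lower, with 6 and 7 adjusted over the list alone (camera adjusted p = 0.858). The quinone reductase gene obr1 rose from 120947 ± 16692 to 419959 ± 117462, though it lies wholly within an opposite-strand non-coding RNA, and the heat shock gene ssa1 from 15776 ± 2442 to 38423 ± 13840. The metallothionein gene zym1 fell from 1928 ± 181 to 756 ± 427, with a log2 change from -2.08 to -0.86 when single libraries were left out, and gst2 at 1.26 did not pass (1.96 without set2d replicate 1, 0.56 without set2d replicate 2). The call of ssa1 was lost without set2d replicate 1 and that of zym1 without set2d replicate 2. Of 22 DNA damage repair and checkpoint genes 3 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.613). The checkpoint kinase gene chk1 rose from 1150 ± 42.7 to 2435 ± 475, and 57.9% of it overlaps meu27 on the opposite strand. The changes of the end-joining genes pku70 and lig4 were both 0.55, and the replication checkpoint kinase gene cds1 fell by 0.49, with opposite-strand non-coding RNAs over 65.1% of pku70 and 48.9% of cds1. The calls of pku70, lig4 and cds1 were lost without any one of the 4 libraries, and that of chk1 without WT replicate 2 and without set2d replicate 2. Of 24 DNA replication factor genes orc1 and cdc20 were higher, by 0.97 and 0.87, the same 2 adjusted over the list alone, while cdc23 at 0.39, with nearly all of it overlapped by a non-coding RNA, and psf1 at -0.29 did not pass (camera adjusted p = 0.825). The call of cdc20 was lost without set2d replicate 2, and 85.2% of orc1 overlaps a non-coding RNA on the opposite strand.

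None of 14 G1/S genes regulated by the MBF transcription factor passed the limma test, among them cdc18 and cdt2 at -0.43, mrc1 at 0.34 and cdc22 at -0.24 (1 higher and 2 lower at an unadjusted p under 0.05, 0 adjusted over the list alone, 0 by limma without a trend, camera adjusted p = 0.30, and 0.0468 without WT replicate 2). Without WT replicate 1 cdc18 was at -0.25 and cdc22 at -0.04, and without set2d replicate 2 cdt2 was at -0.21. The gene mrc1 lies wholly within an opposite-strand non-coding RNA. None of 9 core histone genes passed it either, among them hhf1 at -0.39, hta2 at -0.32, hhf2 at 0.31 and hht3 at -0.30 (1 higher and 2 lower at an unadjusted p under 0.05, 0 adjusted over the list alone, 0 by limma without a trend, camera adjusted p = 0.317). The values of hhf1 and hta2 were -0.58 and -0.64 without WT replicate 1 and -0.20 and -0.0042 without WT replicate 2. Of 14 genes of the H3K36 pathway, histone chaperones and the Clr6 deacetylase complex, 1 was higher, also adjusted over the list alone, the Clr6-associated gene cph1, from 7203 ± 245 to 13284 ± 2926, a call lost without set2d replicate 1 (camera adjusted p = 0.858). The values of pst2, prw1 and hip1 were 0.37, -0.31 and -0.17 and did not pass, and prw1 lies wholly within cta5 on the opposite strand. Of 7 genes used as auxotrophic markers, arg3 rose by 0.51, a call lost without any one of the 4 libraries. Adjusted over the list alone 2 were higher (camera adjusted p = 0.102). These genes could report a difference in strain background only where it changes their transcript level. Their values therefore do not show that the backgrounds match. The values of leu1, ura4 and his3 were 0.47, 0.28 and 0.18 and did not pass, and 90.6% of his3 overlaps alg2 on the opposite strand.

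**Figure D3:**
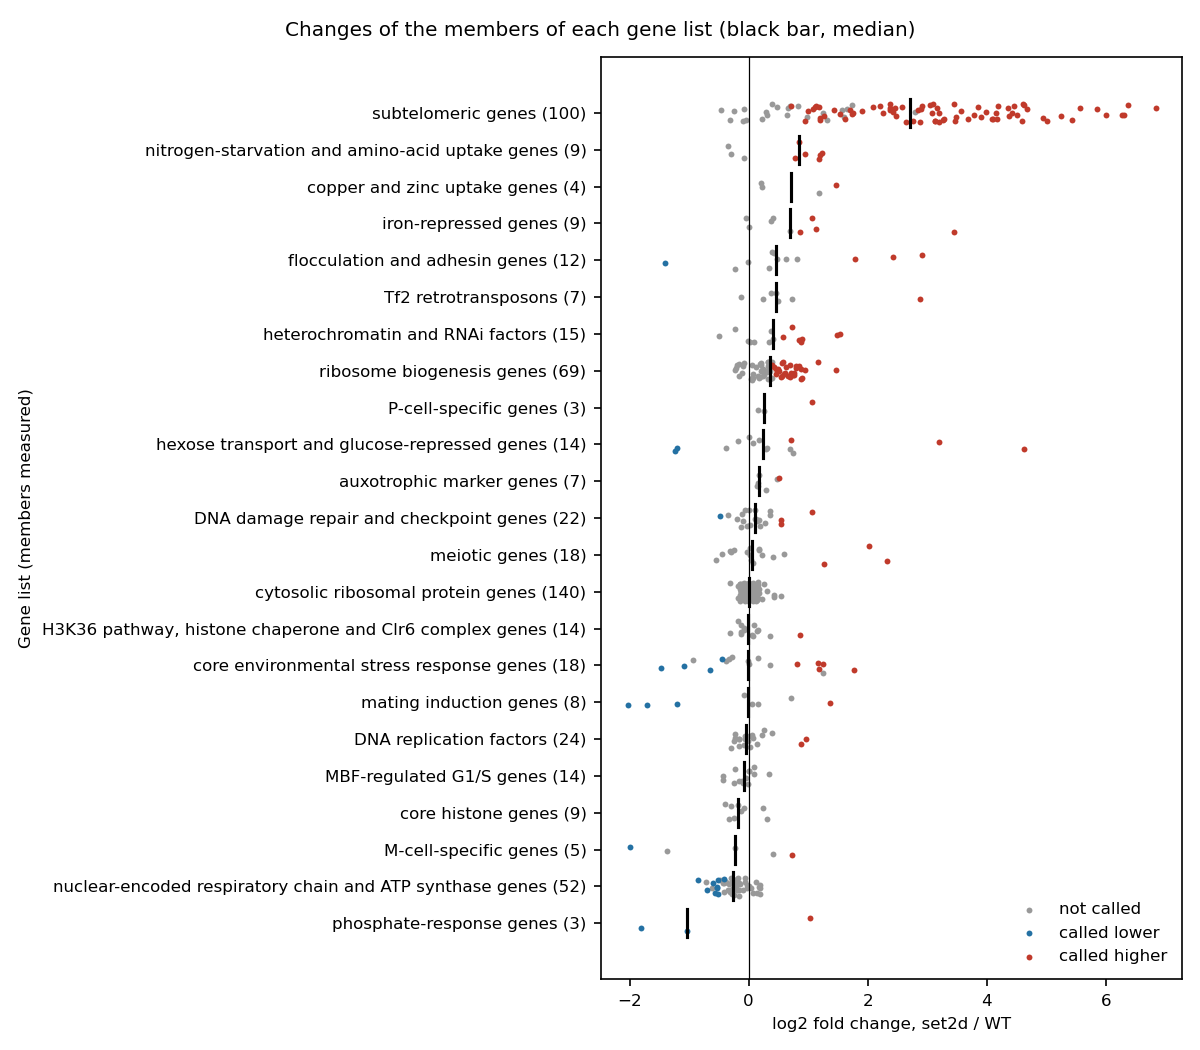
Log2 fold change (set2d over WT) of each measured member of 23 gene lists fixed before the data were examined, each point 1 gene from 2 WT and 2 set2d libraries, with the number of members in brackets and the median as a black bar. Red and blue points passed the limma test over all genes. The subtelomeric list has a median of 2.71.

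Non-coding RNA genes were called higher at a share close to that of coding genes. Of 1440 tested 188 were higher, or 13.1% (95% exact binomial interval 11.4 to 14.9), against 562 of 5068 coding genes, or 11.1% (10.2 to 11.99). The odds ratio was 1.20 (Fisher's exact test, two-sided, p = 0.0442, 0.155 after adjustment over 4 tests), so the difference did not pass the correction, and the ratio was 0.991 without set2d replicate 1. For genes lower, 49 non-coding RNAs and 134 coding genes gave an odds ratio of 1.30 (Fisher's exact test, p = 0.125, adjusted 0.167). That ratio varied between fits, being 3.91 by limma without a trend. It was 2.48, 2.97 and 1.95 without WT replicate 1, WT replicate 2 and set2d replicate 1, and 1.22 without set2d replicate 2. With a replicate block by number its direction was reversed. Over 200 kb from the ends the shares higher were 9.91% and 8.77% (odds ratio 1.14, Fisher's exact test, p = 0.232). The list had 191 higher and 55 lower adjusted over the list alone, and a camera adjusted p = 0.30. Besides prl61, SPNCRNA.1304, SPNCRNA.1695 and SPNCRNA.446, all near the ends of chromosome II, rose by 4.45, 4.10 and 3.86 on the log2 scale, and 60.3% of SPNCRNA.1695 overlaps fub2 on the opposite strand. Of the 1440, 936 overlap a coding gene, and the strand setting of the counting is not given in the sources used here. Since reads of overlapping genes appear to have been counted for both, a similar share in the classes is partly built in. Of 338 non-coding RNAs that overlap no coding gene and lie over 200 kb from the ends, 14 were higher, or 4.14%, and 21 lower.

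Of 83 tested ribosomal, transfer, small nuclear and small nucleolar RNA genes 5 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.825). Genes of these classes held 0.0191% and 0.0199% of all normalized counts in WT replicates 1 and 2. In set2d replicates 1 and 2 they held 0.0356% and 0.0347%. Mitochondrially encoded transcripts held 0.000401% to 0.000495%, floor values included. Few of their reads were thus counted, and the changes may not stand for the whole RNA. The small nucleolar RNA snR30 rose from 4365 ± 598 to 21442 ± 1901 normalized counts (log2 change 2.30, SE 0.14, limma adjusted p = 5.88e-05). The 5S ribosomal RNA gene SPRRNA.12 rose by 2.44, a call lost without set2d replicate 1, and SPRRNA.40 at 2.41 did not pass (1.17 without set2d replicate 1, 3.64 without set2d replicate 2). Of 7 tested Tf2 retrotransposons Tf2-11 rose from 36.2 ± 4.76 to 267 ± 13.7, the only one also when adjusted over the list alone. These elements are near-identical, so their values are uncertain. As annotated, Tf2-11 lies at 100 to 150 kb from the right end of II, a distance at which 36.7% of genes on I and II were higher. Tf2-9, Tf2-10 and Tf2-13 at 0.72, 0.49 and 0.45 did not pass (camera adjusted p = 0.30). None of 6 tested mitochondrially encoded transcripts passed the limma test (0 at an unadjusted p under 0.05, 0 adjusted over the list alone, 0 by limma without a trend, camera adjusted p = 0.613). Among these SPMIT.02, SPMIT.05, SPMIT.11 and SPMIT.01 had log2 changes of 0.69, 0.66, 0.58 and 0.49, with 2 of the 6 at the floor in both WT libraries. Without single libraries SPMIT.02 ranged from 0.22 to 1.17, SPMIT.05 from 0.087 to 1.23 and SPMIT.11 from -0.0176 to 1.17, low without set2d replicate 2 and high without set2d replicate 1, and SPMIT.01 from 0.077 without WT replicate 1 to 0.90 without WT replicate 2.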

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

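The settings with a pseudocount of 1, without genes with a near-identical copy, with genes above the floor in all 4 libraries only, and without genes within 100 kb of the ends were chosen after seeing the data. The planned edgeR and DESeq2 fits were not run, because whole counts could not be recovered in 3 libraries. Over all settings, results counted as unchanged were 33 of 34 for position, 387 of 414 for lists, 1736 of 1858 for single named genes and 20 of 32 for feature class. For named genes this means the same direction and call. For the other kinds, a result that passed in neither fit was counted as unchanged whatever its direction. Counts stayed within 1.5 times in 49 of 64 results over all genes and 719 of 828 of list members. The cause of a change was not tested except where fewer libraries or genes were tested.

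Counts of genes higher and lower were 499 and 103 by limma without a trend. With single libraries left out they ranged from 324 to 488 and from 45 to 86, and genes lower by a log2 change of at least 1 from 25 to 59. Leaving out genes near the ends left 181 higher by at least 1. Quantile normalization called 574 genes higher and 275 lower, 754 of them shared with the 951, and median-ratio rescaling 719 and 229. Median-ratio rescaling moved the median log2 change by -0.03 and quantile normalization by -0.08.

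A replicate block by number called 1380 genes higher and 847 lower, and all 951 calls were among these. Deviations of same-numbered libraries correlated across genes at a Pearson r of 0.451, but with 2 pairs, and a shared title prefix whose meaning the labels do not give, this does not show that the numbers pair the samples. Under the replicate block the phosphate and the copper and zinc lists had adjusted p = 0.00471, the odds ratio of genes lower near the ends was 0.192, and that of non-coding RNAs lower was 0.821, reversed.

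The flocculation list lost its call at adjusted p 0.0503 with a pseudocount of 0.5, 0.0531 with 5, 0.0506 with 1, 0.0503 without a filter, 0.108 with a mean of at least 50, 0.0521 without a trend, 0.0979 without genes with copies, 0.103 with genes above the floor in all libraries and 0.298 without genes near the ends. Without single libraries it ranged from 0.00742 to 0.138, and the nitrogen-starvation list from 0.0016 to 0.101, with calls lost without set2d replicate 1 (0.0567 and 0.0592) and set2d replicate 2. Without genes near the ends the nitrogen-starvation list was at 0.0651, the iron list at 0.0843 and the subtelomeric list, with 3 members left, at 0.999 in the opposite direction. Lists that gained a call without a single library ranged from 0.00168 to 0.40 (phosphate, gained at 0.0468 and 0.00168 without WT replicates 1 and 2), from 0.0126 to 0.211 (copper and zinc, gained at 0.0468, 0.0126 and 0.0391 without all but set2d replicate 1), from 0.0468 to 0.839 (MBF, gained without WT replicate 2) and from 0.0181 to 0.352 (auxotrophic, gained without set2d replicate 2). Ribosomal protein genes ranged from 4.53e-13 to 0.691, down without set2d replicate 1 and up at 6.86e-07 without set2d replicate 2.

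The odds ratio of non-coding RNAs higher was no longer past 0.05 at 1.18 without a filter, 1.09 with quantile normalization and 1.15 without genes near the ends, and ranged from 0.991, reversed, to 1.20 without single libraries. That of non-coding RNAs lower passed at 3.91 without a trend, and ranged from 1.22 to 2.97 without single libraries, passing in all but the one without set2d replicate 2. With single libraries left out the change of ctr4 ranged from -0.302 to 0.767 and that of ctr5 from -0.0197 to 0.432, reversed without set2d replicate 1, and that of SPMIT.11 from -0.0176 to 1.17, reversed without set2d replicate 2. Of 80 named genes that passed, the log2 change of 2 moved by over 1.5 times without at least 1 library. More of the 80 lost the call, where having fewer libraries also lowers the power.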

Other observations

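The genes in the next 2 paragraphs were chosen after their values were seen, and the tests, and their limits, of copies, of extra or missing chromosome ends and of other strain differences were chosen after the result was seen.

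Away from the chromosome ends, coding genes with no near-identical copy also changed by more than 3-fold. The N-acetyltransferase gene SPBC1271.07c rose from 833 ± 17.3 to 5441 ± 352 normalized counts (log2 change 2.71, limma adjusted p = 7.14e-05), with 55.3% of it overlapped by SPNCRNA.1345. The flavin oxidoreductase gene SPBC23G7.10c rose from 368 ± 31.4 to 2372 ± 122, and the exonuclease family gene SPBC609.01 from 607 ± 65.8 to 3837 ± 527. Genes of uracil metabolism that lie close together, urg1 and urg2, rose by 2.39 and 2.13 on the log2 scale. The dehydrogenase gene SPCC663.08c rose by 2.19, but it lies wholly within SPNCRNA.1213. Among regulators, the mediator subunit gene med13 rose from 1945 ± 54.1 to 6652 ± 1284 and the DNA translocase gene rhp1602 from 3596 ± 202 to 12341 ± 238.

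Decreases over 200 kb from the ends were fewer, 124 coding genes against 410 that were higher. The kinetochore protein gene cnp3 fell from 16753 ± 3052 to 6523 ± 706 normalized counts (log2 change -1.35, limma adjusted p = 0.00107). It lies beside abp2, which fell by 1.43, and near elc1, which fell by 1.45, and SPNCRNA.1673, one of the largest decreases, overlaps abp2. The kinase gene byr1 of the mating pathway fell by 1.14, but it lies wholly within SPNCRNA.674.

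Genes near the ends of chromosomes I and II were higher in set2d. Reads shared between copies are argued against by the 87 of 104 genes without a near-identical copy that were higher, or 83.65% (75.1 to 90.2), and ends missing from the WT strain by the 88.99% of genes without a copy that were above the floor in both WT libraries. Genes far from the ends at the same mean level over the 4 libraries had a median log2 change of -0.03153 (range over levels -0.13 to 0.13). This argues only against a shift shared by all genes of a mean level. A scaling fitted across genes could centre such a median by itself, and levels within each group were not matched. Level-dependent scaling as such was therefore not decided. A uniform gain of copies over the whole 100 kb as the whole cause is argued against by the spread of changes within each end. A gain of only part of an end could also spread the changes, and this was not tested. Among genes above the floor in all libraries and without a copy, the smallest interquartile range was 0.8485, at the left end of I (bootstrap interval 0.559 to 1.46, against up to 0.52 from error alone, and 0.748 to 2.02 against 0.609 with all its genes), which did not clear the first limit set, 1, and was then held against error alone. With 1.0 strain per genotype, loss of set2 and another difference between the strains cannot be told apart, and both may contribute.

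Non-coding RNAs were among the calls. For the 274 that lie at least 90% within an opposite-strand coding gene, their log2 changes and those of the coding gene had a Spearman rho of 0.8667 across genes, and 59 of 71 called ones had a partner called the same way. This is consistent with reads of the coding gene being counted for the non-coding RNA, though a shared change of both transcripts would look alike. Of 338 non-coding RNAs over 200 kb from the ends that overlap no coding gene, 14 were higher, or 4.142% (2.28 to 6.85), against 8.77% of coding genes. More of the 338 were lower, 21, where 124 of 4674 coding genes were lower, or 2.65%. That difference in genes lower was not tested. The share higher lay below the bound of 0.5 times the coding share set for such counting. Its interval reached above that bound, so these stay open. A change of antisense transcription in set2d was not tested, since the strand setting is not given in the sources used here.

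Among coding genes over 200 kb from the ends, long ones were more often higher, from 4.78% in the shortest quartile of length to 13.5% in the longest. The Spearman rho of log2 change and gene length over these 4674 genes was 0.11, but 0.002 in number 1 and 0.22 in number 2. Between the set2d replicates its size was 0.2172, so a length bias between libraries may account for it. Within quartiles of mean level rho went from 0.18 in the lowest to -0.007674 in the highest, so the level of the genes stays open. No biological explanation was excluded or shown.

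A hypothesis that coding genes higher in set2d lie next to each other away from the ends was tested and not borne out. There were 36 neighbouring pairs of such genes that do not overlap, against a mean of 27.8 and a 99th percentile of 40 in 10000 shuffles of the calls.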
